A study of Tulipa gesneriana with 15 samples.

How the data were processed

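Whole flowers of the garden tulip (Tulipa gesneriana) were collected at 5 stages, and total RNA was sequenced from 3 libraries per stage, 15 libraries in all. The order runs from buds through partial and then full blooming to senescence, early and then late. The labels do not say whether the 3 libraries of a stage came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

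The authors deposited 1 table of FPKM values (fragments mapped per unit of feature length and of library size), written to 2 decimals, with 1 column per library. That unit is read from the name of the table and from its values, which are not whole numbers. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 were used. The notes available here give no role or order for these tools. The reference sequence, its annotation and any filter are not given in the sources used here. The table lists 76388 identifiers under a gene column. It pairs none of them with a gene name, a position or a function, and it does not say whether 2 identifiers can be copies or transcripts of 1 gene. They are called genes here, as in the table. Of them, 3238 are listed at 0 in every library.

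Each column was matched to its library by the column code in the labels, and every value column was used. FPKM values carry no read counts, and low values did not fall on whole steps, so the depth of each library is unknown and no counting interval is given. Sums of FPKM ranged from 861035 to 1094997 per library. An exact 0 in such a table can be a failed estimate, so a gene at 0 is described only as listed at 0. No 2 libraries held identical values.

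Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with the mean-variance trend, over all 15 libraries, so that the stages share 1 estimate of the spread. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 47326. A moderated F test compared the 5 stages. Contrasts compared each stage with the one before it, and late senescence with full blooming. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Genes past the F test were put in the stage of their highest mean. Genes past the F test were also counted that rose or fell at all 4 steps. A gene was called stage-restricted when it was at 1 or more in all 3 libraries of 1 stage and under 0.1 in all 12 others. Genes changed on opening and in late senescence were counted against the overlap of independent lists, since these 2 comparisons share no library.

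The script was tested on simulated data for late senescence against full blooming, with 47326 genes given normal noise around the real means, with the fitted spreads. Changed genes were drawn from those with a mean over 2 on the log2(FPKM + 1) scale. Of 100 genes changed by 1 on the log2 scale, 37 were recovered, and of 100 genes changed by 2, 79 were recovered. No call had the wrong sign, and 8 unchanged genes were called. Far fewer genes changed in this simulation than were called in the data, which makes the adjusted threshold stricter. All simulated libraries also had noise of the same size, so these figures do not give the recovery in the real comparison.

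The tests between stages, the comparisons, the classes and the alternatives were fixed before the data were examined. Alternatives were another pseudocount, no filter and a stricter filter, median-ratio scaling and quantile normalization, a block for the replicate number, fits on 2 groups only, library quality weights, no trend, a minimum change, and leaving out each library in turn. A further pair of alternatives was added after the data were seen. The rule for named genes, for a table without gene names, took from late senescence against full blooming the 2 largest rises and the 2 largest falls among called genes whose libraries do not overlap and whose higher stage has a mean FPKM of at least 10. Gene lists had been written beforehand. They could not be matched to identifiers without names, so no list was tested and no function is given for any gene.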

Results

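Expression was measured by RNA sequencing in whole tulip flowers at 5 stages from bud to late senescence, with 3 libraries per stage. The study's title names petal senescence, but each library was made from a whole flower and so holds RNA of all floral organs. Between 35738 and 42158 genes were at 1 FPKM or more in a library. The mean was 40285 ± 1669 (SD, n = 3) in buds and 38119 ± 1260 in partial blooming. It was 37516 ± 3056 in full blooming and 36903 ± 169 in early senescence. In late senescence it was 41235 ± 800. The sum of FPKM was also highest in late senescence, at 1051865 ± 39944 (SD, n = 3), against 914657 ± 15092 in early senescence. The depth behind these values is unknown, since the table gives no read counts.

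By mean correlation, the libraries followed the order of the stages. Across genes, the median Pearson correlation of log2(FPKM + 1) was 0.94 within stages and 0.81 between stages. Genes are not independent replicates, so these values are descriptions. The mean correlation of buds with partial blooming was 0.87, with full blooming 0.82, with early senescence 0.71 and with late senescence 0.70. Bud replicate 2 went against this order. It correlated at 0.739, 0.723 and 0.741 with the late senescence libraries, and at 0.696, 0.692 and 0.711 with those of early senescence. Early and late senescence, next to each other in time, correlated at 0.82 on average, less than full blooming and early senescence at 0.86. The first principal component held 39.7% of the variance and ran from buds to late senescence. The second held 26.4% and put buds and late senescence on the same side, away from the stages between. Full blooming replicate 3 stood apart from its stage. It correlated at 0.89 and 0.87 with full blooming replicates 1 and 2, which correlated at 0.96 with each other, and at 0.91 on average with the partial blooming libraries.

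**Figure D1:**
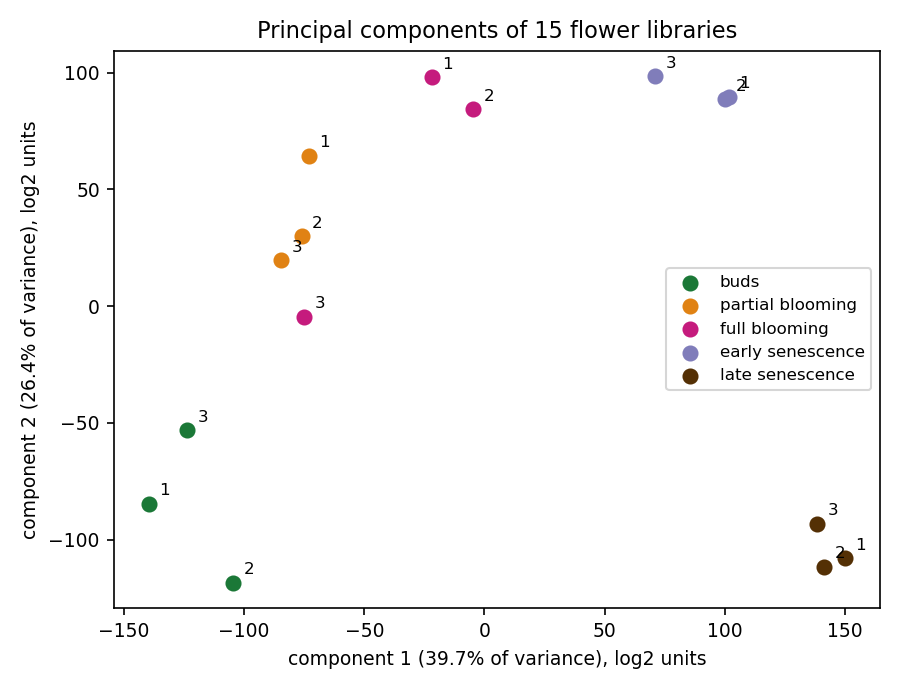
Principal components of log2(FPKM + 1) of 47326 genes, with the first component on the x axis and the second on the y axis, both in log2 units. Each point is 1 library, coloured by stage and numbered by replicate. Full blooming replicate 3 lies next to the partial blooming libraries, and buds and late senescence both lie low on the second component.

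Over the whole course, expression of more than 50% of the tested genes changed with stage, and most of the changed genes were highest at the 2 ends of the series. Of 47326 genes tested, 27431 differed among the 5 stages (58.0%; limma's moderated F test, adjusted p under 0.05). Of these, 20070 spanned at least 1 log2 unit between their highest and lowest stage means. Late senescence was the highest stage of 9495 genes and buds of 8779. Early senescence had 4298 such genes, partial blooming 2820 and full blooming 2039. The early senescence class held 6753 genes with median-ratio scaling and 6736 with quantile normalization, which gave 7866 for buds and 6690 for late senescence. The bud class was also the larger of these 2 with library quality weights (11854 against 10989), without full blooming replicate 3 (10897 against 10355) and without bud replicate 3 (9167 against 9065).

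The classes also traded places as a share of all expression. Genes highest in buds held 43.3% ± 0.626 (SD, n = 3) of the summed FPKM in buds, 24.7% ± 2.02 in partial blooming and 12.2% ± 1.02 in early senescence. Genes highest in late senescence held 15.2% ± 1.2 in buds, 26.6% ± 2.50 in early senescence and 45.6% ± 3.28 in late senescence. Genes highest in early senescence held 27.6% ± 0.196 there and 14.4% ± 2.01 in late senescence. Genes highest in full blooming held 17.8% ± 3.91 at that stage, the widest spread of a class at its own peak, and 5.93% ± 0.618 in late senescence. Since the classes were chosen by where their means are highest, these shares show how much of the expression each class held, and are not a test of its course.

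**Figure D2:**
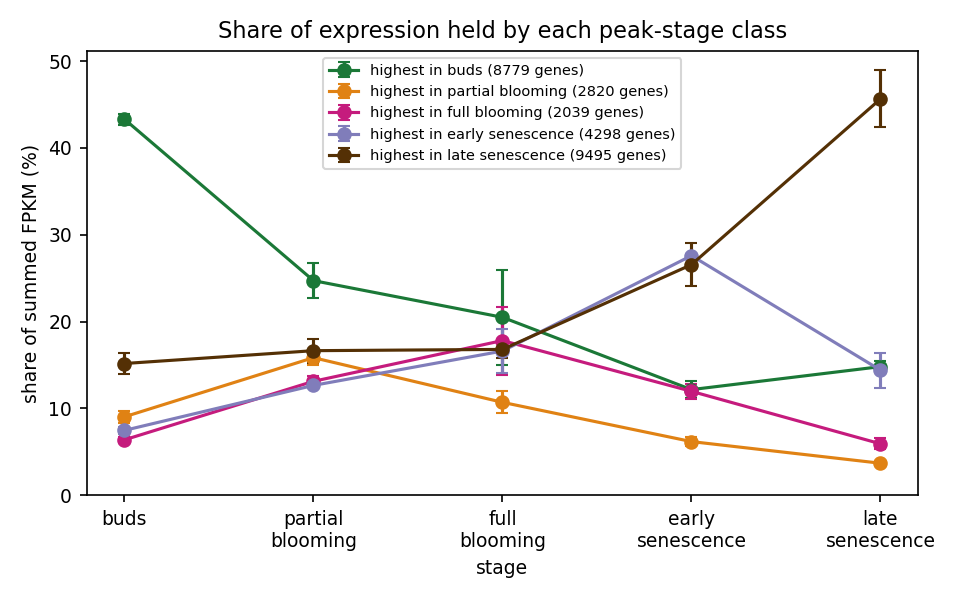
Share of summed FPKM (%, y axis) held at each stage (x axis) by genes past the 5-stage test, grouped by the stage of their highest mean. Points are means of 3 libraries and bars are SD. The bud class falls from 43.3% to 12.2% by early senescence, and the late senescence class reaches 45.6%.

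Genes that moved one way through all 4 steps were more frequent than if all orders of the stages were equally frequent. Of the 27431 genes past the 5-stage test, 1286 rose at every step and 1305 fell at every step, against 228.6 expected in each direction if the 120 orders of 5 stage means were equally frequent. The rising genes held 2.75% ± 0.216 (SD, n = 3) of the summed FPKM in buds and 16.2% ± 2.10 in late senescence, with a median change of 1.69 on the log2 scale. The falling genes held 8.01% ± 0.408 in buds and 1.40% ± 0.141 in late senescence, with a median change of -1.37. Since these genes were chosen by their courses, the shares and median changes show size and are not a test. No single step of these genes was required to pass a test. Genes share the same libraries, so orders need not be equally frequent where no steady course exists. Genes highest in buds and lowest in early senescence, which is no steady course, numbered 5654. Single other orders were not compared.

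The first comparison, partial blooming against buds, addressed which genes change as the flower opens. It called 3131 higher and 3639 lower genes, 14.3% of those tested (limma, adjusted p under 0.05). The median change was 1.14 on the log2 scale among the higher genes and -1.04 among the lower genes. At a change of at least 1 log2 unit, 1815 genes were higher and 1953 lower. Higher and lower genes numbered 3854 and 6222 without full blooming replicate 3, which enters through the shared spread, 2393 and 2267 without bud replicate 1, 2254 and 1706 without bud replicate 2, 2116 and 1573 without partial blooming replicate 1, and 2205 and 2126 without partial blooming replicate 2. Which list was larger also changed with a pseudocount of 0.1 (3190 higher, 2875 lower), with quantile normalization (3962 and 3200) and with median-ratio scaling (3412 and 2982), which moved the median change of all genes from -0.13 to -0.03.

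From partial to full blooming, the fewest genes of any step were called. The test found 464 higher and 331 lower genes, 1.68% of those tested, with median changes of 1.27 and -1.28 on the log2 scale. At an unadjusted p under 0.05, 6486 genes passed. With library quality weights, 2600 genes were higher and 4495 lower. Without full blooming replicate 3, 1113 genes were higher and 1730 lower, and fitted on these 6 libraries alone the comparison called 42 higher and 33 lower genes. Leaving out other libraries gave, for higher and lower genes, 232 and 130 without partial blooming replicate 1, 255 and 155 without replicate 3, 246 and 182 without full blooming replicate 1, and 190 and 136 without replicate 2, while the lower genes numbered 176 without partial blooming replicate 2 and 534 without late senescence replicate 2.

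At the onset of senescence, from full blooming to early senescence, 4155 genes rose and 3241 fell, 15.6% of those tested. The median change was 1.17 among the genes that rose and -1.03 among those that fell, and 2523 and 1681 of them changed by at least 1 log2 unit. Of the genes tested, 32.4% had no overlap between the libraries of the 2 stages, against 10% by chance for 3 libraries against 3. Without early senescence replicates 1 and 2 in turn, 2104 and 2088 genes fell, and on these 6 libraries alone 2010 fell.

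The step from early to late senescence called the most genes of the 4 steps. It found 9105 higher and 4683 lower genes, 29.1% of those tested, and 50.4% of tested genes had no overlap between the 2 stages, against 10% by chance. The median change was 1.15 on the log2 scale among the higher genes and -0.95 among the lower genes. At a change of at least 1 log2 unit, 5368 genes were higher and 2175 lower. The balance of higher and lower calls depended on how the libraries were scaled. As deposited, the median of all tested genes lay 0.19 higher in late senescence and 66.0% of called genes were higher. With median-ratio scaling that median was 0.02 and 49.1% were higher (6725 higher, 6959 lower), and with quantile normalization the median was -0.07 and 40.4% were higher (5859 higher, 8636 lower). Without early senescence replicate 3, 6053 genes were higher. The labels do not say which plants the libraries of a stage came from, so any difference between plants would enter these calls, and those of late senescence against full blooming, together with the stage.

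Against full blooming, late senescence had 10398 higher and 6338 lower genes, 35.4% of those tested. Changes of at least 1 log2 unit were found for 6474 higher and 3256 lower genes. The median change was 1.20 on the log2 scale among the higher genes and -1.02 among the lower genes. The scaling moved this split as well, from 62.1% of called genes higher as deposited to 51.1% with median-ratio scaling (8433 higher, 8064 lower) and 42.7% with quantile normalization (7510 higher, 10089 lower). The median change of all genes was 0.15 as deposited, 0.03 with median-ratio scaling and -0.08 with quantile normalization, and fitted on these 6 libraries alone the comparison called 4004 lower genes.

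**Figure D3:**
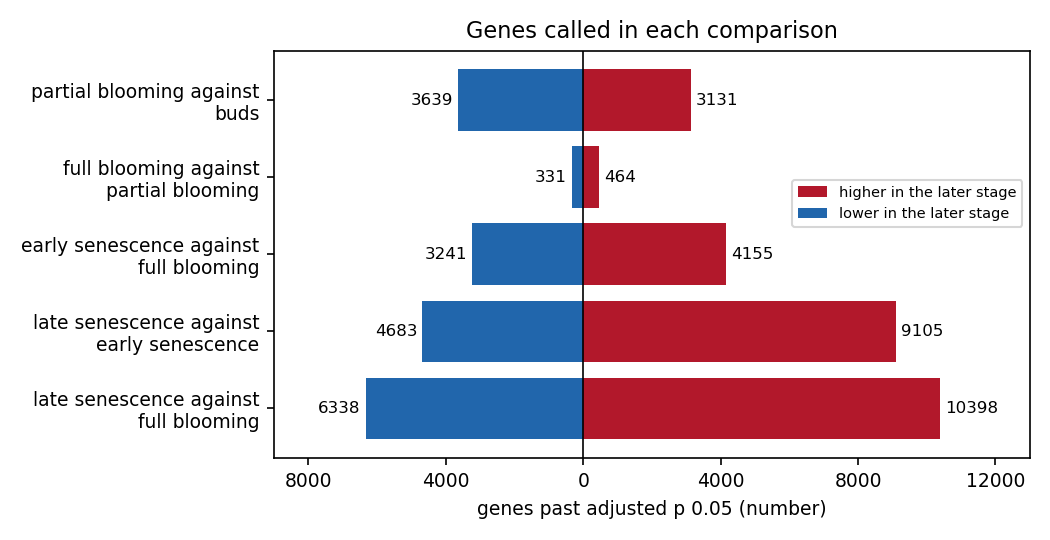
Number of genes called in each comparison (x axis, genes past adjusted p 0.05 in limma), with genes higher in the later stage to the right and lower to the left. Late senescence against early senescence has the most calls of the 4 steps, and full blooming against partial blooming the fewest; with median-ratio scaling the late senescence step has 6725 higher and 6959 lower genes.

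Among the called genes of late senescence against full blooming, the largest rises began before late senescence. F01.PB322 was at 0, 1.56 and 2.03 FPKM in full blooming, at 509 ± 301 (SD, n = 3) in early senescence and at 2042 ± 234 in late senescence. Its log2 change from full blooming to late senescence was 10.005 ± 0.72 (SE), with a limma adjusted p of 5.01e-07. F01.PB8436 was at 13.3 ± 9.95 FPKM in buds, 0.603 ± 0.547 in full blooming, 283 ± 158 in early senescence and 449 ± 109 in late senescence. Its log2 change was 8.16 ± 0.71 (SE; limma adjusted p of 2.58e-06). With a pseudocount of 0.1 the log2 changes of these 2 genes were 11.49 and 9.80. All 3 late senescence libraries lay above all 3 of full blooming in both genes. In both, early senescence replicate 3 was the lowest library of its stage, at 182 and 100.5 FPKM.

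The largest falls came between early and late senescence. F01.PB13351 was at 464 ± 102 FPKM (SD, n = 3) in buds, 2432 ± 402 in partial blooming, 3474 ± 924 in full blooming and 3017 ± 375 in early senescence. It is listed at 0 in all 3 late senescence libraries, so no fold is given. Its limma adjusted p was 2.54e-12. In bud replicate 2 it was at 363 FPKM, against 462 and 567 in the other buds. F01.PB13351 is among the 164 genes at 1 FPKM or more in the 3 stages before late senescence and under 0.1 in its libraries. For that set, described further on, failed estimates tied to the stage and a difference between plants remain open. F01.PB16570 rose from 10.5 ± 1.21 FPKM in buds to 441 ± 43.0 in partial blooming and 1654 ± 624 in full blooming. It was at 973 ± 175 in early senescence and at 0, 15.3 and 0 in the late senescence libraries, all under the 3 of full blooming. Its log2 change from full blooming to late senescence was -9.28 ± 0.78 (SE; limma adjusted p of 1.93e-06). With values of 0 the size depends on the pseudocount and on single libraries: it was -11.52 with a pseudocount of 0.1, -10.62 without late senescence replicate 2, and -8.61 without late senescence replicate 1 or 3. The table gives no name, position or function for these 4 genes.

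**Figure D4:**
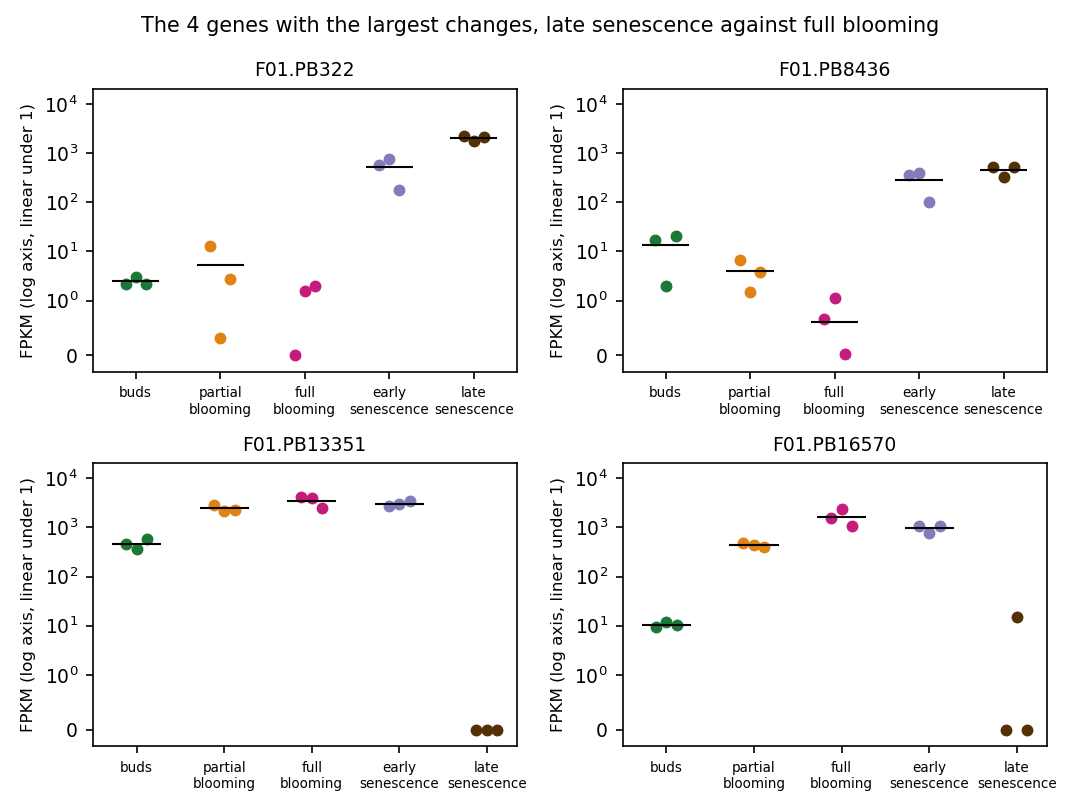
FPKM per library (y axis, log scale, linear under 1) at each stage (x axis) of the 4 genes named by the rule. Points are libraries and lines are means of 3 libraries, drawn only where no library is at 0. F01.PB322 and F01.PB8436 rise at early senescence, while F01.PB13351 is listed at 0 in all 3 late senescence libraries after a mean of 3017 in early senescence.

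Genes that changed on opening tended to change the other way in late senescence. Of the 3131 genes that rose from buds to partial blooming, 1220 fell from early to late senescence, against 309.8 expected from independent lists, and 273 rose again, against 602.4 expected. Of the 3639 genes that fell on opening, 1304 rose in late senescence, against 700.1 expected, and 142 fell again, against 360.1 expected. These comparisons share no library. Over all 47326 genes the log2 changes of the 2 steps correlated at -0.35 across genes. The genes that fell on opening and rose late held 12.8% ± 0.567 (SD, n = 3) of the summed FPKM in buds, 2.50% ± 0.0288 in early senescence and 6.18% ± 0.407 in late senescence. The genes that rose on opening and fell late held 4.03% ± 0.476 in buds, 16.1% ± 3.82 in full blooming and 5.61% ± 0.824 in late senescence. Since both sets were chosen by these changes in the same libraries, the shares show their size and are not a test of the reversal. The genes that fell on opening and rose late numbered 2805 without full blooming replicate 3, 850 and 556 without bud replicates 1 and 2, 550 and 747 without partial blooming replicates 1 and 2, and 844 and 869 without early senescence replicates 1 and 3. Those that fell at both numbered 227 without full blooming replicate 3, 86 without bud replicate 2, 69, 72 and 91 without partial blooming replicates 1, 2 and 3, and 90 and 88 without early senescence replicates 1 and 3. Which opposite pair was larger changed with the scaling. With median-ratio scaling 967 genes fell and then rose, and 1559 rose and then fell. With quantile normalization these were 877 and 1938. Across all 28 settings the ratio of observed to expected stayed above 1 for both opposite pairs, from 1.68 to 6.26, and under 1 for both same-direction pairs, from 0.31 to 0.73.

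Genes seen in the libraries of a single stage were almost all seen in those of late senescence. A difference between plants cannot be told apart from the stage for these genes. There were 61 genes at 1 FPKM or more in all 3 late senescence libraries and under 0.1 in all 12 others. Buds had 3 such genes, early senescence 1, and partial and full blooming 0. Random sets of 3 libraries from different stages had at most 4, over 100 sets drawn. In the reverse direction, 125 genes were under 0.1 in all 3 late senescence libraries and at 1 or more in all 12 others. Such losses numbered 19 for buds, 7 for early senescence, 2 for partial blooming and 0 for full blooming. The random sets had at most 2 such losses. Failed estimates that fall on libraries regardless of stage are thus argued against for these losses, while failed estimates tied to the stage are not. Of 137 genes at 1 or more in late senescence and under 0.1 in the 9 libraries of the 3 stages before it, 58 were at 1 or more in bud replicate 2, against 5 and 7 in bud replicates 1 and 3. Without bud replicate 2, 121 genes were restricted to late senescence, and without late senescence replicate 3 there were 107. Fewer libraries make the rule easier to meet, and the counts of 0 to 3 in the other stages reached at most 7 (buds, without bud replicate 3).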

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

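Leaving out 2 libraries together, and leaving out the all-or-none genes of late senescence, were chosen after the data were seen; the other alternatives were fixed before. Of 787 values recomputed, 701 kept their call or stayed within 1.5 times (within the spread for correlations) and 86 moved. Counts cannot reverse, but the split of calls did turn. Between early and late senescence, 66.0% of called genes were higher as deposited and 40.4% with quantile normalization. On opening, 46.2% were higher as deposited and 53.4% with median-ratio scaling. In late senescence against full blooming, these were 62.1% as deposited and 42.7% with quantile normalization. In full against partial blooming, 58.4% were higher as deposited, 39.1% without full blooming replicate 3 and 36.6% with library quality weights. Each named gene kept its direction and stayed past the threshold under each alternative run for it. The stricter filter, the absence of a filter, the absence of a trend, the replicate block and leaving out the all-or-none genes moved no value that far. The causes of the shifts below were not tested, except that a minimum change passes fewer genes by construction and that fewer libraries make a rule on all libraries easier to meet.

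With median-ratio scaling, 6753 genes were highest in early senescence. With quantile normalization these were 6736, while 5859 genes were higher and 8636 lower in late than in early senescence, and 10089 were lower in late senescence than in full blooming; 1938 rose on opening and fell late, and 245 fell at both. Fits on 2 groups gave 42 higher and 33 lower genes in full against partial blooming, and 2010 and 4004 lower genes in early and late senescence against full blooming. Library quality weights, lowest for full blooming replicate 3 at 0.197, gave 6276 lower genes on opening, 2600 higher and 4495 lower in full against partial blooming, and 6664 higher and 5531 lower in early senescence against full blooming. They gave 503 genes that rose at both opening and late senescence, 3010 that fell and then rose, and 251 that fell at both. With a minimum change of 1 log2 unit, higher and lower genes numbered 1815 and 1953 on opening, 2523 and 1681 in early senescence against full blooming, 5368 and 2175 from early to late senescence, and 6474 and 3256 in late senescence against full blooming. The class highest in full blooming then held 1349 genes, and the overlaps of opening and late senescence were 150 (rose, rose), 522 (rose, fell), 656 (fell, rose) and 33 (fell, fell). The median correlation within stages was 0.894 with a pseudocount of 0.1 and 0.911 as Spearman's rho.

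Leaving out each library in turn gave 1573 to 6222 lower genes on opening, 190 to 1113 higher and 130 to 1730 lower in full against partial blooming, 2088 to 3535 lower in early senescence against full blooming, and 6053 to 11145 higher in late than in early senescence. It gave 550 to 2805 genes that fell on opening and rose late, and 69 to 227 that fell at both. Stage-restricted genes ranged from 3 to 7 in buds, 0 to 1 in partial blooming, 0 to 1 in full blooming, 1 to 3 in early senescence and 61 to 121 in late senescence. Without full blooming replicate 3 and bud replicate 2 together, 1138 genes were higher and 1584 lower in full against partial blooming, and restricted genes numbered 1 in partial blooming, 1 in full blooming and 126 in late senescence.

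The replicate numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated between -0.37 and 0.37, and 4 of 15 libraries correlated best with their own number. Among libraries numbered 3, which after buds all leaned towards the stage before them on a measure chosen after the data were seen, 5 of 10 pairs correlated above 0. With the replicate block, 25901 genes differed among the stages, against 27431, and no count of calls moved by over 1.5 times. Fits on 2 groups give no value for the 5-stage test and its classes, and stage-restricted counts were recomputed only for scaling and left-out libraries. Gene set tests and their alternatives were not run, since no identifier has a name, and count tests were not run, since the values are not counts. Depth is unknown here, so it cannot be said which low values it limits.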

Other observations

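The most abundant gene of late senescence led 3 of the 5 stages. It held 0.389% ± 0.0674 (SD, n = 3) of the summed FPKM in buds, 1.48% ± 0.0711 in full blooming, 3.49% ± 0.353 in early senescence and 4.12% ± 0.675 in late senescence. A second gene led buds and partial blooming, at 1.22% ± 0.384 and 1.13% ± 0.0827, and held 0.467% ± 0.111 in late senescence. The 100 most abundant genes together held 19.9% ± 0.736 in buds and 23.1% ± 1.19 in late senescence. These genes, and the courses that follow, were singled out after their values were seen. Among genes past the 5-stage test, the most frequent course was highest in buds and lowest in early senescence, with 5654 genes (20.6%). The next was highest in late senescence and lowest in partial blooming, with 3045 genes (11.1%).

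In the tests that follow, those on gains and losses in late senescence and on full blooming replicate 3 were chosen after the result was seen. The exceptions were fixed before their own result was seen. They include the drop in bud replicate 2 over that expected from the late-only genes, and the spread of ratios between late libraries. The gene sets and the bud library that these 2 use were picked from the data. The other exceptions are both tests on genes that return in late senescence, and the splits of the libraries.

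Late senescence differed from the 3 stages before it by genes listed on one side and at or near 0 on the other: 137 genes were at 1 FPKM or more in its 3 libraries and under 0.1 in those 9, with a median of 12.4 FPKM, and 164 went the other way, 158 of them listed at 0 in all 3 late libraries. As the cause of both sides together, added RNA of another organism or cell type is argued against by the losses. The 125 genes under 0.1 in the late libraries and at 1 or more in all 12 others were 6.58 times the highest count of another stage (19, buds), although zeros can be failed estimates. These losses do not bear on the source of the 137 late-only genes. The ratios of the late-only genes between late libraries spread 1.86 times as widely as those of other genes of like level. This argues against a single added source of these genes with the same expression in each late flower. It cannot weigh against a single source whose own expression differs between flowers, since that would also widen the ratios. Several added sources were not tested. The 58 late-only genes at 1 or more in bud replicate 2 were 8.29 times the count of the median bud library, at 52.3% of their late level. For these genes, that argues against senescence alone only if this bud held no senescing tissue, which was not tested. For the other 79, senescence alone cannot be told apart from a difference between plants, because each late library comes from the late stage. A candidate explanation is a genetic background that the late senescence flowers share in part with bud replicate 2, which listed 21 genes under 0.1 together with late senescence, against at most 5 in any other library; the labels give the same genotype, wild type, for the bud and late libraries, and such a background would also enter the 13788 calls against early senescence and the 16736 against full blooming. One even share of that background in bud replicate 2 is argued against: of the genes at or near 0 in late senescence and at 1 or more in buds 1 and 3, 16.6% were under 5% of those buds there, against 0.529% of other genes of like level, while their median was 53.5%; the drop of these genes over that expected from the late-only genes, 36.7, decides nothing, because the median late-only gene stood at only 1.78% of its late level.

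Full blooming replicate 3 correlated better with partial blooming, at 0.909 on average, than with its own stage, at 0.883. With buds it averaged 0.871. Among single libraries, it correlated at 0.874 with partial blooming 1 and at 0.894 with bud replicate 1, the latter above either full blooming library. A swap or mixing with a bud library was not tested. A label swap with partial blooming 2 or 3 is argued against, because both correlated better with their own stage than with full blooming 1 and 2, by at least 0.0294 in mean r, and either exchange lowered the mean r within groups (0.926 and 0.921, against 0.929 as labelled) and called at most 3 genes. A swap with partial blooming 1 cannot be told apart from correct labels: that library too correlated better with its own stage, by 0.0215, but the exchange raised the mean r within groups to 0.937 and the calls from 795 to 1765. Tissue at an earlier point of opening may contribute, since across genes the difference of full blooming 3 from 1 full blooming library correlated at 0.389 with partial blooming minus the other, but this fell short of the set bar of over 2 times the highest value of another stage, 0.210. On that measure replicate 3 was above 0 in each of the 4 stages after buds (0.144 in partial blooming, 0.389, 0.210 in early and 0.164 in late senescence). The 3 values of a stage sum to 0 by the way the measure is built, so at least 1 library per stage cannot lie under 0. That the 8 libraries of replicates 1 and 2 were under 0 is therefore no separate evidence. A single wrong label was not tested.

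Genes that fell on opening rose again in late senescence in 1304 cases. Bud RNA mixed into the late libraries is argued against: among 149 genes at a bud mean of at least 100 FPKM and under 5% of it in early senescence, the 10th percentile of the late to bud ratio was 0.169 of the median, where an even admixture was taken to need at least 0.5. The median ratio was 12.4%, from 2.10% at the 10th percentile to 37.2% at the 90th, and 37 genes stayed under 5%. Scaling as the whole cause is argued against by 967 genes with median-ratio scaling. A return of bud expression in senescence may underlie the pattern. The count over that of independent lists was 1.70 without bud replicate 2 and 1.88 without the all-or-none genes, against 1.86. Without bud replicate 2 the count itself was 556, with 1 library fewer in the test. The excess over independent lists thus does not rest on bud replicate 2 alone, but how much of the count does is not settled. A background in the late flowers alone and a change of organ make-up were not tested for this pattern.

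Other splits of the libraries bear on whether the counts could arise by chance. For the 5 stages, 1 of 100 splits, the real one, gave as many genes (27431, against 2382 as the highest of the others). A chance assignment of these libraries to the stages is thus argued against, as far as 100 splits can show. Differences between plants, or technical likeness, that the libraries of a stage share remain open. Each pair of stages allows 10 splits, too few for a share under 0.05. In 4 comparisons 1 of 10 splits, the real one, gave as many genes: the real count and the highest other were 6770 and 3 for partial blooming against buds, 7396 and 1 for early senescence against full blooming, 13788 and 2 for late against early senescence, and 16736 and 2 for late senescence against full blooming. For full against partial blooming, 2 of 10 splits gave as many: the split that exchanges full blooming 3 with partial blooming 1 called 1765, against 795, which points to a structure of these 6 libraries that the stage labels do not follow.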
